A study of Caenorhabditis elegans with 2 samples.

How the data were processed

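Chromatin immunoprecipitation followed by sequencing was carried out on whole young adult Caenorhabditis elegans collected 63 hours after L1 synchronization. The worms carried an integrated transgene that expresses the T-box transcription factor TBX-9 fused to GFP and FLAG, and an antibody against GFP was used, per the labels. The series holds 2 libraries, described as biological replicates 1 and 2 of 1 group. A control experiment is named in the labels and was not analysed here.

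The 8 peak lists used here came from the authors: on each of 2 builds, ce11 and ce10, a list of relaxed peaks and background for replicate 1, for replicate 2 and for both libraries pooled, and a list of optimal peaks past the irreproducible discovery rate (IDR) threshold. Relaxed lists were made from alignments of the libraries and of a control, and the IDR lists from the relaxed lists, per the text files deposited with the samples. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal value of each peak is the authors' own and is in the signal column of the narrowPeak format; whether it is scaled for depth is not stated. The deposited −log10 q per peak follows the narrowPeak format, and the deposited p column holds no values. The summit is the deposited offset from the peak start. The signal value was used to describe, rank and filter peaks within a list. It was also correlated between the replicate lists and its sorted values were set side by side between the 2 builds; since its scaling is not stated, levels in these comparisons are descriptive. Of the 169 ce11 IDR peaks, 26 had the same start and end as a pooled relaxed peak and 0 had the same signal value, so comparisons of signal values between the IDR list and the relaxed lists are not reported.

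No read counts were part of the files used, so the sequencing depth of the libraries is unknown. The relaxed lists held 25659 ce11 peaks for replicate 1, 30000 for replicate 2 and 30000 for the pool. The precision of shares is set by the 169 IDR peaks, and intervals are 95% Wilson intervals that cover counting error only. Where a share was 0, the limit is that of 3 peaks.

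Coordinates are those of the ce11 files, written counting from 1, and were set against the Ensembl release 115 annotation and the RefSeq sequence of WBcel235, the assembly also called ce11. No ce11 peak ended beyond the length of its chromosome. No coordinate was converted between builds, and genes and sequence were used for ce11 alone.

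The main background was the pooled relaxed ce11 list without the peaks that overlap an IDR peak, 29779 peaks. Shares were compared by 2-sided Fisher's exact tests, and families of tests were adjusted by Benjamini-Hochberg at 0.05. A coding start was a protein-coding transcript start within 1000 bp of the summit. Noncoding classes were counted within 250 bp of the summit over 6 classes. The T-box site AGGTGTGA was searched on both strands within 100 bp of the summit. For 16 fixed gene lists, protein-coding genes with an IDR summit within 1000 bp of a start were compared with the 10290 that had any relaxed or IDR summit there; 2 list names were not found in the annotation. Replicates were compared through the 169 strongest peaks of each list, with chance from 1000 random placements on the same chromosomes. Fisher's exact tests treat peaks as independent and compare peaks within this 1 group, so they carry no information on spread between animals.

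Genes were named by a fixed rule: the protein-coding gene with the closest start within 1000 bp for the 25 IDR peaks with the highest signal, up to 4 members of each fixed list with the strongest IDR peak, up to 3 genes of each noncoding class past its test, and tbx-9, tbx-8 and unc-119. Groups, comparisons, gene lists, the naming rule and most alternatives were fixed before the data were examined; those added later are named in the closing section. A rank-matched comparison of noncoding classes, added later, shuffled the IDR label 10000 times among nuclear pooled relaxed peaks within bins of 50 ranks. It covered 189 relaxed peaks that overlap an IDR peak, which is not all of those that do. Alternatives changed the distance to a start, the motif and its window, the position used for a peak, the background, the build, the number of top peaks and the overlap that counts as shared, and used each replicate alone. The interval of the rank correlation was taken from Fisher's z.

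The tests were tried on simulated peak sets. Of 20 random sets of 169 peaks, 0 were called for tRNA genes, and 20 of 20 sets with 15% of peaks planted at tRNA genes were called. The random sets were drawn from the whole pooled relaxed list and not by strength, so they do not cover sets picked for strong signal. Planted motifs were found in 25 of 25 windows, and a translation list with 20 planted genes, more than the count observed, was called in 20 of 20 sets. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.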

Results

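Sites enriched by immunoprecipitation of GFP-tagged TBX-9, a T-box transcription factor that acts in embryonic morphogenesis, were examined in transgenic young adult worms. The ce11 list of optimal IDR peaks held 169 peaks, most of them 390 bp wide. Of these, 62 lay in a top peak of both replicates. The strongest, with a signal value of 311.5, lay on chromosome V from 8500363 to 8500752, beside the snoRNA gene ZK994.7. The weakest had a signal value of 106.4. The q-values deposited for these peaks ran from 0.0467 to 0.0940. There were 2 libraries of 1 group and no second condition, so the comparisons are between replicates and between kinds of peak.

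Of the 169 IDR peaks, 15 lay within 25 kb of tbx-9. Of the 154 outside that region, 32 had a tRNA gene and 33 a snoRNA gene within 250 bp of the summit, and 77 had a coding start within 1000 bp, classes that overlap. When each peak was put in 1 class only, noncoding genes before coding starts, 16 fell to other noncoding genes, 49 to coding starts and 10 to coding gene bodies, and 14 to none of these. By annotation at the summit, 36.1% were intergenic (95% interval 29.2 to 43.6), 21.3% lay in noncoding exons, 18.3% in coding exons, 14.2% in introns, 7.10% in 3′ UTRs and 2.37% in 5′ UTRs.

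The replicates shared strong peaks only in part. Of the 169 strongest peaks of replicate 1, 74 overlapped one of the 169 strongest of replicate 2, 43.8% (95% Wilson interval 36.5 to 51.3). Random placement gave a mean of 0.214 and at most 3 in 1000 placements, and none reached 74, for a permutation p of 0.0010, the smallest they can give. Placements were uniform along each chromosome, so this p does not allow for sites where strong peaks recur for reasons other than the tagged protein. All but 1 of the IDR peaks overlapped a relaxed peak of replicate 1 and all 169 one of replicate 2, at median ranks of 124 and 135. Across the 168 IDR peaks with a peak in both, Spearman's rho of the signal was 0.412 (95% interval 0.278 to 0.530). This is a correlation across peaks, which are not independent replicates. Ranks are over all chromosomes, and 13 mitochondrial peaks stood above every nuclear peak in replicate 1 and none in replicate 2. The peak of the snoRNA genes C51F7.3 and C51F7.4 stood at rank 1 in replicate 2 and at rank 19 in replicate 1, which is rank 6 among its nuclear peaks. The peak at the 3′ end of tbx-9 stood at rank 123 in replicate 1 and rank 26611 in replicate 2.

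**Figure D1:**
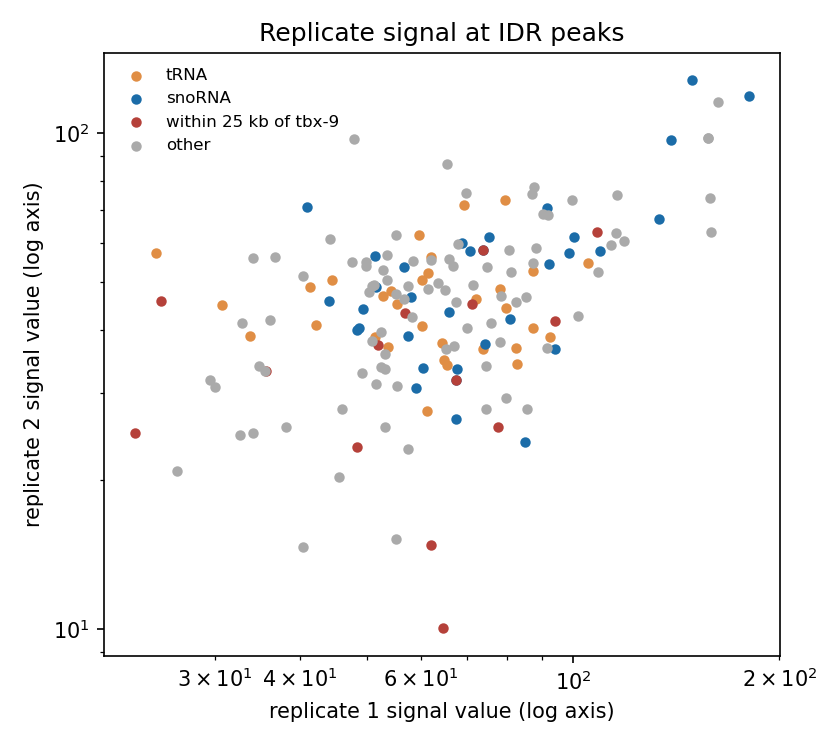
Deposited signal value of the strongest overlapping relaxed peak in replicate 1 (x, log axis) and replicate 2 (y, log axis) for each of the 168 IDR peaks with a peak in both, coloured by class. The points spread widely around a rising trend, with a rho of 0.412.

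Noncoding genes, above all tRNA and snoRNA genes, lay at IDR peaks more often than at background peaks. A tRNA gene lay within 250 bp of 32 IDR summits, 18.9% (95% Wilson interval 13.7 to 25.5), against 1.62% of the relaxed background, and a snoRNA gene within 250 bp of 33 summits, 19.5% (14.3 to 26.2) against 0.551%. For snRNA genes the shares were 2.37% and 0.282%, and for other noncoding RNA genes 26.6% and 7.43%. These classes overlap: with each peak counted once, after the tbx-9 region, tRNA and snoRNA genes, 16 peaks fell to all other noncoding classes together. Fisher's exact test with Benjamini-Hochberg adjustment over the 6 classes gave adjusted p of 1.45e-23 for tRNA, 2.3e-38 for snoRNA, 0.00237 for snRNA and 8.74e-14 for other noncoding RNA. miRNA genes (1 peak, adjusted p of 0.483 by Fisher's exact test) did not pass, and no peak lay at an rRNA gene, which allows a share of up to 1.78%. Against the 500 strongest relaxed peaks outside the IDR list, of which 25% lay at tRNA genes and 5.20% at snoRNA genes, the snoRNA class alone passed, with an adjusted p of 8.37e-07 by Fisher's exact test. Matched on pooled rank in bins of 50, relaxed peaks that overlap an IDR peak lay at snoRNA genes in 17.5% against a matched mean of 15.3% (one-sided permutation p of 0.0877), and at tRNA genes in 34 of 189 peaks against a matched mean of 41.1.

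Named examples follow the classes. Among snoRNA genes, which guide chemical modification of other RNAs, ZK994.7 (V, 8500579 to 8500645) had the peak with signal 311.5, with its summit in an intron, and C51F7.3 (V, 12303708 to 12303783) and C51F7.4 shared a peak of 278.2. Among tRNA genes, M02F4.t1 (tRNA-Gly) and M02F4.t2 (tRNA-Glu) on X shared a peak from 3035920 to 3036309 with signal 161.2, and C02B4.t2 (tRNA-Tyr, X) had 160.9. The snRNA class, which rests on 4 peaks and on the biotype in the annotation alone, was led by sls-2.4, a spliced leader gene (I, 4172206 to 4172315), with 238.4, R07E5.16 with 183.3 and sup-6 with 148.4. rpr-1, the RNA component of RNase P (I, 13463955 to 13464207), had 298.3. T03F7.14 had 243.0, at a peak that also lay at a snoRNA gene, and R12E2.18 shared the sls-2.4 peak.

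**Figure D2:**
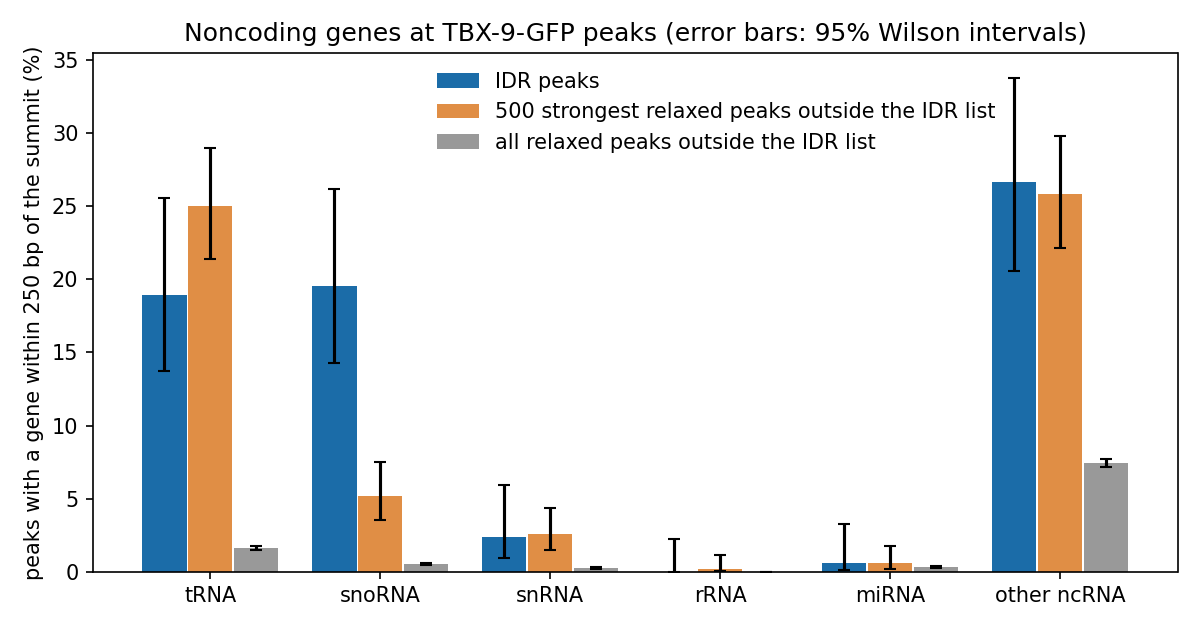
Share of peaks with a gene of each class within 250 bp of the summit (y, percent) for the 169 IDR peaks, the 500 strongest relaxed peaks outside the IDR list and all 29779 relaxed peaks outside it; error bars are 95% Wilson intervals. IDR peaks stand at 18.9% for tRNA and 19.5% for snoRNA genes, and the strong relaxed peaks at 25% and 5.20%.

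Coding starts were about as common at IDR peaks as in the background. Of the 169 summits, 86 lay within 1000 bp of a coding start, 50.9% (95% Wilson interval 43.4 to 58.3), against 47.1% of the relaxed background, and Fisher's exact test gave a p of 0.354. Random placements on the same chromosomes gave a mean of 40.5%, with a permutation p of 0.00599. Within 500 bp the shares were 36.7% and 28.6%, with a p of 0.0263 by Fisher's exact test.

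Of the 25 strongest peaks, 14 had a coding start within 1000 bp. These genes were ints-8, an Integrator subunit (signal 298.3, shared with rpr-1), mdt-26, a Mediator subunit (II, 5661181 to 5665243; 263.6), egg-5, which acts at the oocyte-to-embryo transition (238.4, shared with sls-2.4), kin-14, a predicted tyrosine kinase with its summit in the 5′ UTR (178.7), ced-9, the Bcl-2 homologue that protects cells from death (III, 10335172 to 10337522; 178.6), and F44E5.4, of the Hsp70 family (178.4). The others were pot-3, a homologue of telomere-binding proteins (174.7), D2096.7 (173.8), rpl-3, a large ribosomal subunit protein (172.8), Y75B12B.11 (168.8), tasp-1 (168.6), cfim-2, of the mRNA cleavage machinery (168.2), dnj-13, a DnaJ cochaperone (165.7), and lmd-2 (165.1). The peaks at Y75B12B.11 and cfim-2 also lay at snoRNA genes and that at dnj-13 at another noncoding gene, each with its summit in a noncoding exon. The ced-9 peak is 1 of the 15 within 25 kb of tbx-9. Replicate ranks were low for pot-3, 252 in replicate 1 and 1453 in replicate 2. For D2096.7 they were 369 and 5. The other peaks of these 14 genes stood at rank 177 or higher up in both replicates.

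Among the 16 fixed lists, translation genes passed the test. Of the translation genes in the background, 6 had an IDR summit near a start, 5.94% against 0.923% of other genes, with an adjusted p of 0.00698 by Fisher's exact test. They were rpl-3 (172.8), rps-6 (155.2), rpl-35 (124.9) and rpl-20 (121.4), together with rpl-43 and rps-17, all ribosomal proteins. The rps-6 summit, at 13953349 on I, lay beyond the annotated end of that gene at 13953203, and 813 bp from the closest of its transcript starts. With a distance of 500 bp the count was 3 and the adjusted p by Fisher's exact test 0.557, and in the higher-signal part of the list, 85 peaks, the count was 2 and the adjusted p 0.891. The gene lists were not compared with genes near the 500 strongest relaxed peaks outside the IDR list. Whether signal strength alone gives the translation excess was therefore not tested. Of 22 stress and chaperone genes, 2 had a summit near a start, hsp-60, the mitochondrial chaperonin (133.9), and hsp-1, a constitutive Hsp70 (118.0), with an adjusted p of 0.152 by Fisher's exact test. Of 21 neuronal genes, 1 did, snb-1, which encodes synaptobrevin (112.7), with an adjusted p of 0.990 by Fisher's exact test. The start of another gene lay closer to the summit for rpl-20, rpl-43, hsp-60 and snb-1 (syx-18 for snb-1), and the hsp-1 peak also lay at another noncoding gene. The other 13 lists had 0 members with a start within 1000 bp of an IDR summit: the T-box family, the transgene loci, body wall and pharyngeal muscle, epidermis and cuticle, Hox and posterior patterning, intestine, germline, core histones, major sperm proteins, collagens, nuclear hormone receptors and homeobox ceh genes. With about 1% of background genes near an IDR summit, lists of this size could not show a lower share.

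The T-box site was not detected at the summits. AGGTGTGA stood within 100 bp of 0 of 169 IDR summits, which allows a share of up to 1.78%, against 0.453% of background windows, and Fisher's exact test gave a p of 1. The shorter core GGTGTGA was also found in 0 windows, against 1.74%, with a p of 0.126 by Fisher's exact test. GGTGTG stood in 12 windows, 7.10%, against 6.05%, with a p of 0.518 by Fisher's exact test. For AGGTGTGA and GGTGTGA, a share below that of the background was out of reach with 169 peaks.

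The X chromosome held 28 of the IDR peaks, 16.6% (95% Wilson interval 11.7 to 22.9), against 19.7% of the background, with a p of 0.333 by Fisher's exact test. Chromosome III held the most, 40 peaks, followed by IV with 29, II with 28, V with 24 and I with 20. Without the 15 peaks near tbx-9, III held 25.

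The loci named in connection with the transgene differed from each other. At tbx-9 (III, 10340006 to 10341858), 2 IDR peaks lay within 1000 bp, the stronger with signal 120.3 at rank 106, and the strongest pooled relaxed peak stood at rank 172 of 30000. The strongest relaxed peak there in each replicate, which was not the same peak in both, stood at rank 123 in replicate 1 and rank 168 in replicate 2. At tbx-8, the paralogue next to it (III, 10347349 to 10349740), there was no IDR peak and no pooled relaxed peak within 1000 bp; replicate 1 had 1 relaxed peak there, at rank 22736, and replicate 2 had 3, the strongest at rank 3855. At unc-119, the rescue marker of the strain (III, 10902641 to 10908935), the strongest pooled relaxed peak stood at rank 21451. The 15 IDR peaks around tbx-9 spanned III from 10327804 to 10363112, a stretch of 35.3 kb with 11 coding genes that include ced-9, mev-1, spp-1 and umps-1. Elsewhere no window of 50 kb held more than 4 IDR peaks, and even spacing would put 0.0595 of them in this stretch.

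**Figure D3:**
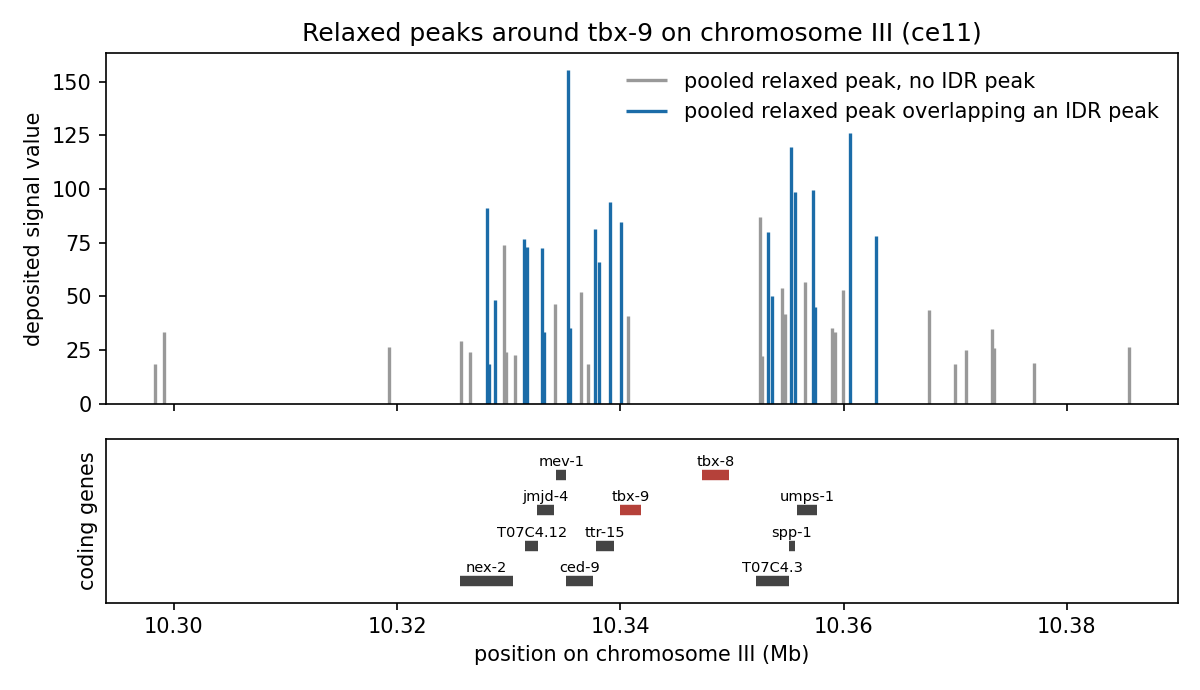
Deposited signal value (y) of pooled relaxed peaks by summit position on chromosome III in ce11 (x, Mb), with peaks that overlap an IDR peak in blue and coding genes of the stretch below. Strong peaks run from nex-2 to beyond umps-1, and the stretch between tbx-9 and T07C4.3, which holds tbx-8, has no pooled relaxed peak but holds 1 IDR peak, from 10344544 to 10344933 with signal 130.0, which is not drawn.

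The list made on ce10 was longer, with 288 IDR peaks against 169 on ce11. Its lowest signal value was 94.2 against 106.4, and both lists began at 311.5. Of the ce10 peaks, 169 had a signal at or above the lowest ce11 value. No difference in the share of peaks per chromosome was detected by a permutation test (p of 0.637).

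**Figure D4:**
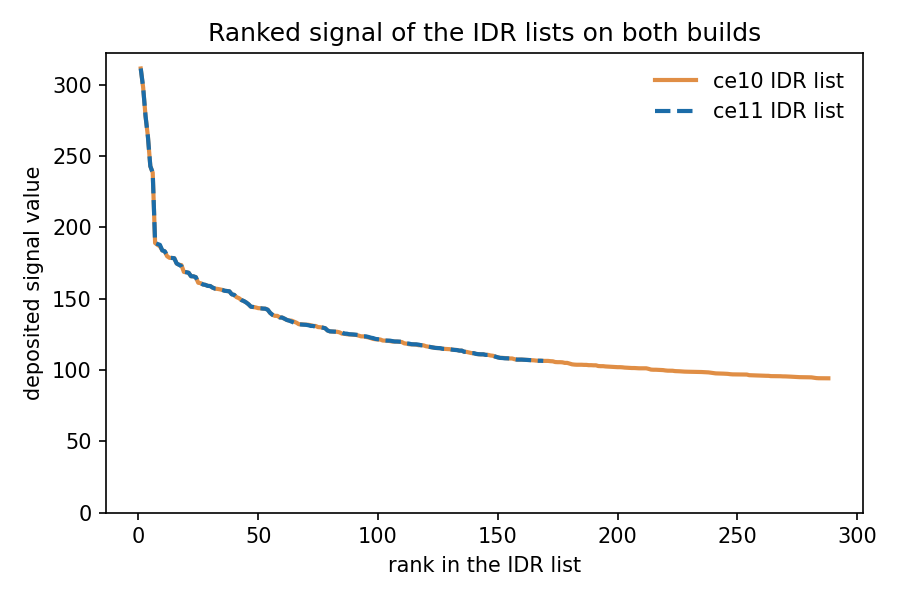
Deposited signal value (y) by rank in the IDR list (x) for ce11 and ce10. The 2 curves lie on each other down to 106.4, where the ce11 list ends, and the ce10 list goes on to 94.2.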

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

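The tests in this part of copy number and motif at the tbx-9 stretch and of signal strength, including the rank-matched ones, and the comparison with the 500 strongest relaxed peaks, were chosen only after the result was seen. The tests of repeated 31-mers and of the B box inside the gene were chosen before their results were seen. The conditions under which copy number, repeated 31-mers, the B box and signal strength count as undecided were made stricter after the results were seen.

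Mitochondrial DNA, on which the IDR list has no peak, carried 14 relaxed peaks in replicate 1, all among the 169 strongest used for the replicate overlap and above the limit of 3 that a count of 0 allows. The strongest had a signal value of 2477, against 180.6 for the strongest nuclear peak of that list. Replicate 2 had 0 mitochondrial peaks, and the pooled list had 10. On nuclear chromosomes alone the overlap was 44.4%, against 43.8%.

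The 15 IDR peaks around tbx-9 may reflect extra copies of that stretch in the transgenic strain. The median signal of relaxed peaks in the stretch was 1.70 times that of the higher 100 kb flank in replicate 1 and 1.83 times in replicate 2. Because the stretch was defined by its IDR peaks, the ratio was also taken without relaxed peaks that overlap one, and was 1.21 and 1.61. Not all values go this way. No pooled relaxed peak lay within 1000 bp of tbx-8, inside the stretch. The strongest pooled relaxed peak at unc-119, the rescue marker, stood at rank 21451. That locus lies outside the stretch, so its rank cannot decide on copies of the stretch. The GGTGTGA core stood in 0 of the 15 windows around these summits, which argues against a match to this core as a common feature of them. Binding without that core stays open, no biological explanation beyond it was tested, and copy number itself was not measured.

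The tRNA and snoRNA peaks could come from reads shared between near-identical genes, but the median share of repeated 31-mers in their windows was 0.0351. That median mixes unlike classes: it was 0 for snoRNA peaks, which argues against shared reads there, and 0.307 for tRNA peaks, between the bounds set in advance. A tRNA gene fills only part of its window, so the upper bound was hard to reach, and 1 of 32 tRNA windows passed it. For tRNA genes shared reads therefore stay open. For both classes together, the answer on signal strength depended on the background: the share exceeded that of non-IDR relaxed peaks at ranks 10 to 3160 by 27.3 percentage points (Fisher's exact test, p of 9.69e-19), and that of the 500 strongest, which was seen first, by 8.26 (Fisher's exact test, p of 0.0568). Neither background matches rank closely. With the IDR label shuffled within bins of 50 pooled ranks, the snoRNA excess was 2.16 percentage points (one-sided permutation p of 0.0877). The first bins hold mostly IDR peaks, so that shuffle had little room for an excess, and strength stays open for snoRNA genes. For tRNA genes the difference was -3.78 (one-sided permutation p of 0.9785). The share among the 500 strongest relaxed peaks outside the IDR list was also above that of the IDR list, 25% against 18.9%. Beyond what strong peaks show, no tRNA excess was therefore seen in the IDR list. The B box, a biological explanation for the snoRNA peaks, is weighed with the other observations. Binding by TBX-9 itself was not tested, and the control experiment was not analysed here.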

How the results depend on the processing

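The alternatives that leave out the peaks near tbx-9, use the 500 strongest relaxed peaks outside the IDR list as background, take the whole gene body, or drop mitochondrial peaks were chosen after seeing the data. Except where the construction is named, the cause of a change was not tested. Among the values that answer a comparison, 62 alternatives left a test on its side of the threshold, a value within its interval or a count within 1.5 times, while 6 moved a value or count further, 4 reversed a difference and 2 took one past the threshold. The X share, the replicate overlap (37.9% to 44.4%), the correlation (0.305 to 0.466) and the snoRNA excess (14.2 to 23 percentage points) kept theirs under every alternative of this kind; the rank-matched snoRNA test, which did not pass, stands with the closer looks. The number of IDR peaks was 85 in the higher-signal part by construction, 62 when a top peak of both replicates was required, and 288 on ce10. The excess near coding starts was 8.03 percentage points at 500 bp and 3.30 to 9.87 with 1 replicate alone, past the threshold for replicate 1 alone. With the 500 strongest as background it was -7.51, the tRNA excess -6.07, the snRNA excess -0.233 and the miRNA excess -0.00828, and 1 noncoding class passed in place of 4. The T-box difference was 1.05 for GGTGTG and ran from -0.444 to 0.0778 with 1 replicate alone. The count of gene lists past the test fell from 1 to 0 at 500 bp and in the higher-signal part. The neuronal list, with 1 member, went to -0.536 in the higher-signal part, -0.936 at 500 bp and -1.18 to -1.01 with 1 replicate alone. With 1 replicate alone 5 classes passed: the rRNA difference was 0 to 1.18, past the test for replicate 1, and the miRNA difference 0.896 to 1.58, past it for replicate 2. Mitochondrial genes were kept in the noncoding classes, and 14 of the 169 strongest peaks of replicate 1 are mitochondrial. Whether the rRNA difference comes from them was not tested. The miRNA difference was -0.0765 at 1000 bp. No paired analysis was possible because the series holds 1 group. Depth was unknown, and 169 peaks limit every share.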

Other observations

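The tests in this part of X-linked peaks, of the ce10 threshold, of the bases beside snoRNA genes and of transcript ends against strong peaks were chosen only after the result was seen.

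The peaks on X were nearly all at tRNA genes. Of 28 IDR peaks on X, 24 had a tRNA gene within 250 bp, 85.7%, against 8 of 141 on the autosomes, 5.67%, while snoRNA genes lay at 0 of the X peaks and 33 of the autosomal ones. Fisher's exact test gave p of 2.02e-18 for tRNA and 0.00155 for snoRNA. Of annotated tRNA genes 43.5% are on X and of snoRNA genes 9.54%, and of background peaks 3.50% on X and 1.16% on autosomes lay at a tRNA gene.

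A further hypothesis was that IDR summits lie at the ends of coding transcripts. A version with gene ends, which was not the one set in advance, was tried first. It gave an excess of 25.5 percentage points over the background (Fisher's exact test, p of 9.49e-13). The version set in advance used transcript ends. Within 500 bp of a coding transcript end lay 84 of 169 summits, 49.7% against 26.1% of the background, a difference of 23.6 percentage points (Fisher's exact test, p of 9.24e-11). The 500 strongest relaxed peaks outside the IDR list had 52.8% there (Fisher's exact test, p of 0.533), so the excess was not particular to the IDR list.

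A candidate explanation for the snoRNA peaks was an internal promoter of the tRNA type, marked by the B box GTTCRANNC. Inside the gene, the box stood in 1 of 34 snoRNA genes with an IDR peak and in 15 of 312 without, a difference of -1.87 percentage points (Fisher's exact test, p of 1), too few to decide. When 20 bp on either side were searched too, a version that was not the one set in advance and whose result was seen first, the counts were 15 of 34 and 33 of 312 (Fisher's exact test, p of 4.39e-06). Restricted to boxes on the gene's strand that start upstream, they were 13 and 17 (Fisher's exact test, p of 3e-07). That a tRNA-like promoter lies just upstream of these genes is therefore a hypothesis found in these data, and it needs a test on other data.

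The longer ce10 list may be the same ranking with a lower threshold. With no tolerance, 169 ce10 peaks reached the lowest ce11 signal, and sorted signals differed by at most 0.835%. With a tolerance of 0.1%, tried first, the count was 171.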
